A study of Mus musculus with 4 samples.

How the data were processed

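Per the labels, the tissue was bone marrow and the genotypes were C57BL/6-J (Control) and Alb/TGF, with 2 mice each and no treatment. Per the submitters' processing notes, femurs were crushed, cells were passed through a 40 µm strainer, red cells were removed with ACK lysis buffer, and reads of the 10x 3′ gene expression libraries were aligned to mm10 with Cell Ranger, whose version is not given in the sources used here. The deposited unit was integer UMI counts in filtered feature-barcode matrices of 31053 genes, and all values here were computed from these counts. Of the gene identifiers, 31011 (99.9%) were found in GENCODE vM21 (GRCm38), which gave the gene positions. Raw reads were not used here.

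Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs, and doublets were called per library by Scrublet in scanpy 1.11.5 (expected rate 8%) and left out. Of 40926 barcodes 34427 were kept. Doublets made up 3.66%, 2.36%, 0.908% and 3.05% of the barcodes passing the filters in Control 1, Alb/TGF 1, Control 2 and Alb/TGF 2. Median genes per kept cell were 1369, 1451.5, 1311 and 1349 in that order. Clusters came from 2000 variable genes, 30 principal components, 20 neighbours and Leiden at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, seed 1). Globin genes, Myc, Tgfb1, immunoglobulin, T-cell receptor, mitochondrial, ribosomal protein and sex-linked genes were left out of the variable genes. A cluster took the class with the most fixed markers among its top 100 genes by fold over the mean of the other clusters (10 CPM added to each), if at least 3 markers of that class were at least 2-fold higher. It stayed unnamed where a class of another lineage had at least 50% as many markers in the top 100 or any other class had more in the top 10. A shallow cluster with no marker in the top 10 also stayed unnamed, and 3 clusters did in all.

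UMIs were summed per class and library. Classes with at least 30 cells in every library (14 classes) and whole marrow were tested with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood F test) and DESeq2 1.42.0 in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. Shares of classes were tested by the same edgeR model on cell counts, with the total of kept cells as library size. Exact two-sided permutation tests over mice were used for ratios and shares. Fixed gene lists (30) were tested where at least 3 members were measured, by camera in limma 3.58.1 with the preset correlation of 0.01, with the estimated correlation and with fry, adjusted over all lists and classes. The interaction of genotype and class was fitted with library as a block. Intervals for shares are 95% Wilson intervals, and a count of 0 was taken to allow 3 counts.

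Genes were named by a fixed rule. In erythroid classes these were the 10 genes with the largest fold in each direction, and in other classes the 5, among those with an adjusted p under 0.05, a mean log2 CPM of at least 5 and the same direction in both replicate numbers. Where none passed, the 5 with the smallest p are given as values. Unnamed gene models, immunoglobulin variable genes, pseudogenes and sex-linked genes were not named by rank, and 15 erythroid, globin, Myc and TGF-β genes were always named. Of each list described, members with the smallest p are given. The classes, markers, lists, thresholds and the naming rule were chosen before the data were examined.

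The library names of equal replicate number share a code, so the replicate number was used as a block in an alternative fit. Deviations from the group mean correlated between libraries of equal number by −0.173 to 0.432 over 15 fits, and 13 were above 0.1. Those not above 0.1 were erythroblast-like (−0.173) and NK-cell-like cells (−0.0149). The edgeR and DESeq2 steps were tested on simulated data with the dispersion trend of these libraries over expression and 200 changed genes. The changed genes were drawn from those with a log2 mean CPM of at least 5. EdgeR made 6 false calls of 185 in erythroid-progenitor-like, 4 of 94 in erythroblast-like and 9 of 180 in whole-marrow data. With the replicate block it made 10 of 189, 4 of 92 and 11 of 185 in the same order. DESeq2 made 4 of 182, 1 of 71 and 21 of 198, so its whole-marrow calls held the largest share of false ones. False calls were not measured in other single classes. The camera step was tested at a low dispersion of 0.01, with 5 of 50 lists of 30 genes raised 1.5-fold and genes drawn independently. It found 5 of 5 raised lists with the preset and 4 of 5 with the estimated correlation, with 0 false calls in both. Without correlation between genes, this cannot show how often the preset correlation calls falsely in these data. Other tools were numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 in Python 3.11.15, with the R package data.table at version 1.17.8.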

Results

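Bone marrow cells of 4 mice were profiled by droplet-based 3′ single-cell RNA sequencing, which counts transcripts as unique molecular identifiers (UMIs). Libraries Control 1 and Control 2 came from C57BL/6-J mice, and libraries Alb/TGF 1 and Alb/TGF 2 from Alb/TGF transgenic mice, a line in which the promoter of the liver gene albumin drives a TGF-β1 transgene. The labels and the design text describe independent biological replicates, so n = 2 mice per group throughout. The deposited matrices held 58225312 UMIs for Control 1, 47464258 for Alb/TGF 1, 91391196 for Control 2 and 78288332 for Alb/TGF 2. After filtering, 8217, 5826, 10691 and 9693 cells were kept in the same order, with medians of 3866, 4092, 4454 and 4458 UMIs per cell. Clustering gave 35 clusters, of which 32 were named by fixed marker genes as 17 classes, each written here as "like" its type because no cell was sorted. No cluster was named as conventional dendritic cells, eosinophils or endothelial cells, which does not exclude such cells inside other clusters. At the finer clustering 256 cells with the conventional dendritic markers Clec9a and Cd209a split from the plasmacytoid-dendritic-like cells and stayed unnamed, with markers of 2 lineages. Intervals and limits given here cover counting error only, and a limit from a count of 0 bounds cells with a UMI, not cells expressing a gene. The X-inactivation transcript Xist stood at 867, 916 and 867 CPM (UMIs per 10⁶ UMIs of the library or class) in Control 1, Alb/TGF 1 and Control 2 and at 0.163 in Alb/TGF 2, and the Y-linked Ddx3y was counted only in Alb/TGF 2, at 33.1 CPM. Tgfb1 (ENSMUSG00000002603, GRCm38 chromosome 7, 25687002 to 25705077), which encodes the TGF-β1 ligand, stood at 117 and 120 CPM in the kept cells of Control 1 and Alb/TGF 1 and at 51.0 and 52.2 in Control 2 and Alb/TGF 2. Its values thus lay further apart between replicate numbers than between genotypes. The albumin gene Alb had 0 UMIs in all 4 libraries, which allows up to 0.0577, 0.0706, 0.0346 and 0.0407 CPM.

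The series title names defective erythropoiesis, and the first comparison asked whether erythroid cells made up another share of Alb/TGF marrow. Erythroid-progenitor-like cells were those of 2 clusters carrying Klf1, the master regulator of the erythroid program, with early genes such as Car1 and Ermap or later ones such as Hemgn, Rhd and Cpox. Erythroblast-like cells formed 1 cluster rich in Slc4a1, the red-cell anion exchanger, with a median of 62.9% of UMIs from globin genes. The erythroid-progenitor-like share was 2.91% in Control 1 and 6.51% in Alb/TGF 1, but 7.07% in Control 2 and 3.61% in Alb/TGF 2. The erythroblast-like share was 0.535% and 3.36% in the libraries numbered 1, and 2.29% and 0.310% in those numbered 2. Within each replicate number the 95% Wilson intervals of the erythroblast-like share did not overlap, 0.399 to 0.718% against 2.93 to 3.86% for number 1 and 2.02 to 2.59% against 0.217 to 0.441% for number 2, and the direction was opposite between the numbers. Group means were 4.99% ± 2.94 in Control and 5.06% ± 2.05 in Alb/TGF for progenitor-like cells, and 1.41% ± 1.24 and 1.84% ± 2.16 for erythroblast-like cells (SD, n = 2 each). The edgeR log2 fold changes were 0.02 (SE 0.60, adjusted p 0.977) and 0.37 (SE 1.24, adjusted p 0.961). Neither sign was stable: the erythroblast-like value was −0.11 with the replicate number as a block, −0.32 without Control replicate 1 and −2.19 without Alb/TGF replicate 1, and the progenitor-like value was −0.48 without Control replicate 1 and −0.47 without Alb/TGF replicate 1. The marrow had passed through ammonium chloride (ACK) red-cell lysis, so these shares describe the cells that survived it. The Alb/TGF over Control ratio was 1.92 and 0.790 in the early progenitor cluster with Car1 (numbers 1 and 2), 2.69 and 0.296 in the later progenitor cluster with Hemgn, and 6.28 and 0.135 in erythroblast-like cells.

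**Figure D1:**
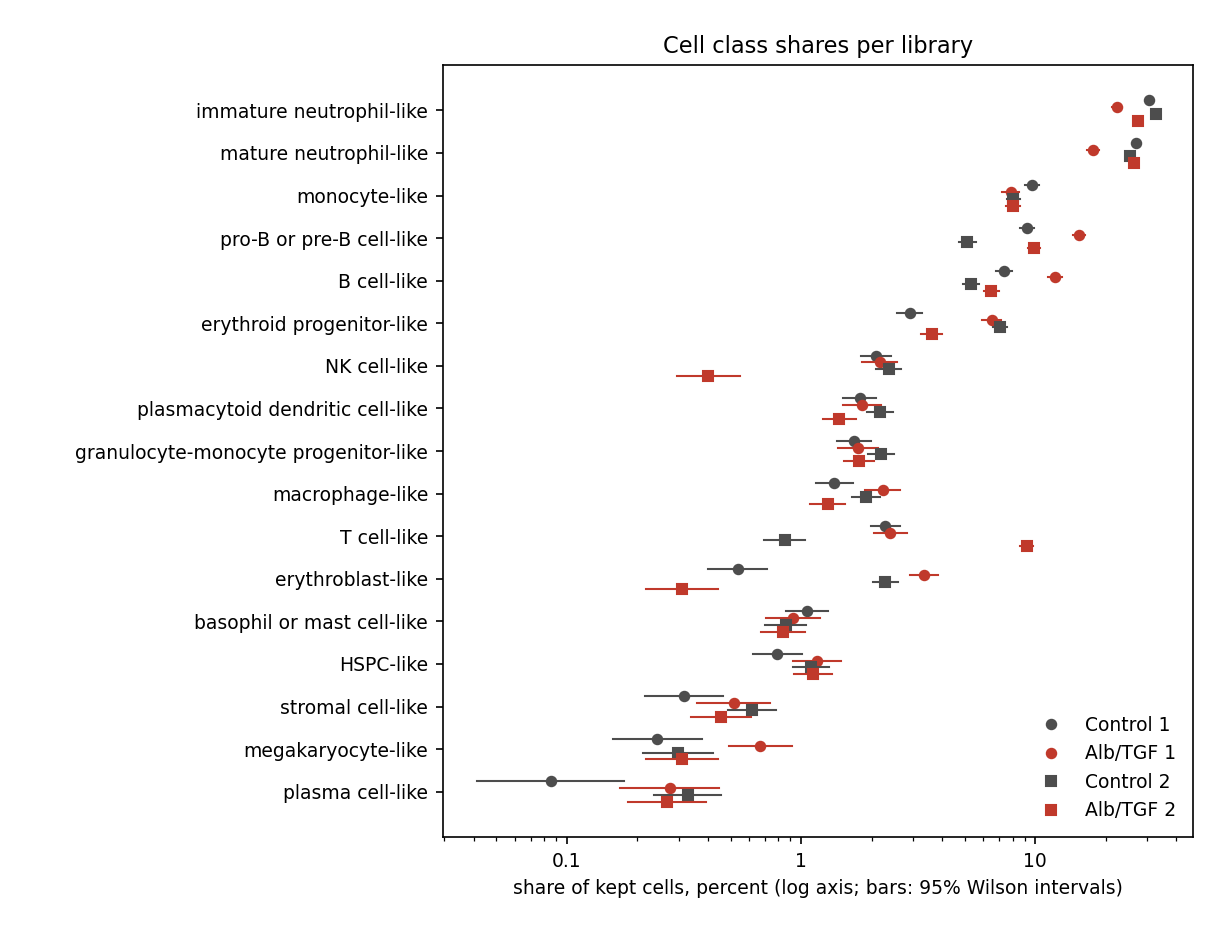
Share of kept cells in each cell class, on a log axis in percent, with 1 point per library, bars of 95% Wilson intervals and n = 2 mice per group. Erythroblast-like cells made up 0.535% and 2.29% of the Control libraries and 3.36% and 0.310% of the Alb/TGF libraries.

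**Figure D2:**
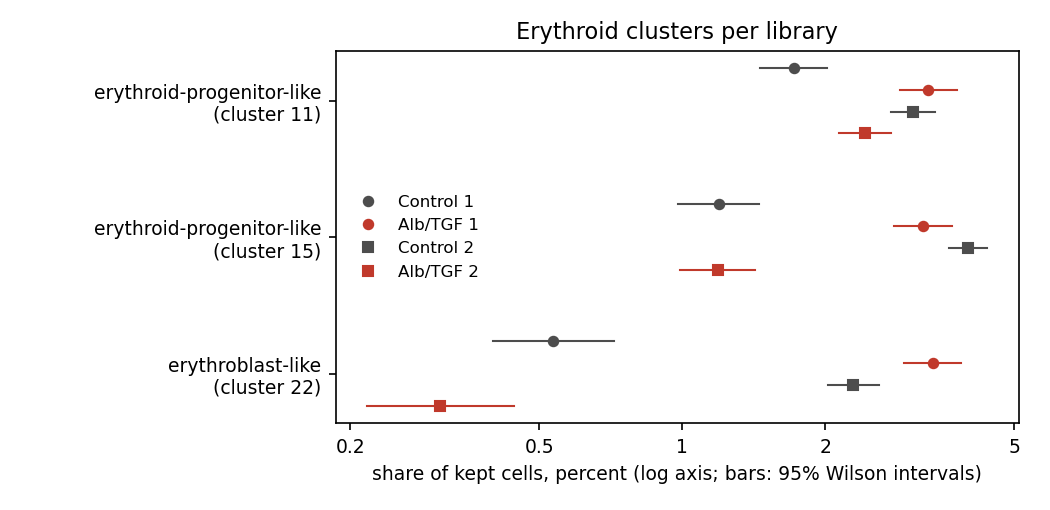
Share of kept cells, on a log axis in percent, of the 2 erythroid-progenitor-like clusters and the erythroblast-like cluster, with 1 point per library and bars of 95% Wilson intervals. The ratio between genotypes went from 1.92 to 6.28 in replicate number 1 and from 0.790 to 0.135 in number 2 along the 3 clusters.

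Among the other classes 5 had higher shares in Alb/TGF of both replicate numbers (pro-B- or pre-B-like, B-cell-like, T-cell-like, HSPC-like and megakaryocyte-like) and 3 lower ones (immature-neutrophil-like, monocyte-like and basophil- or mast-cell-like), none of which passed. HSPC stands for hematopoietic stem and progenitor cells. Pro-B- or pre-B-like cells, named by genes of the surrogate light chain and of receptor rearrangement, made up 7.19% ± 2.90 of Control and 12.6% ± 3.87 of Alb/TGF cells (SD, n = 2 each), with ratios of 1.67 and 1.93. The B-cell-like share was 6.34% ± 1.46 and 9.30% ± 3.97, with ratios of 1.64 and 1.22. Immature-neutrophil-like cells, which carry secondary granule genes such as Camp and Ltf, stood at 31.8% ± 1.56 in Control and 24.9% ± 3.74 in Alb/TGF, with ratios of 0.727 and 0.840. T-cell-like cells stood at 2.29%, 2.40%, 0.851% and 9.18% in Control 1, Alb/TGF 1, Control 2 and Alb/TGF 2, and 842 of the 890 T-cell-like cells of Alb/TGF 2 belonged to a single cluster. Without that cluster the T-cell-like log2 fold change moved from 1.89 to −0.07. None of the 17 classes passed the edgeR test at a false discovery rate of 0.05, and 0 had an unadjusted p under 0.05, with the lowest adjusted p at 0.890. Without Control replicate 2, 1 class passed, plasma-cell-like cells with a log2 fold change of 1.65, a class singled out after its values were seen. In the other 9 of the 17 the replicate numbers moved in opposite directions. With 2 mice per group the smallest two-sided exact permutation p is 0.333, which pro-B- or pre-B-like, T-cell-like, HSPC-like, megakaryocyte-like, immature-neutrophil-like and monocyte-like cells reached.

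The next comparison asked whether the balance of early to late erythroid cells differed between genotypes. Per erythroblast-like cell there were 5.43 progenitor-like cells in Control 1 (239 against 44 cells), 1.93 in Alb/TGF 1 (379 against 196), 3.09 in Control 2 (756 against 245) and 11.7 in Alb/TGF 2 (350 against 30). On the log2 scale the ratio was 2.03 ± 0.58 in Control and 2.25 ± 1.83 in Alb/TGF (SD, n = 2 each), a difference of 0.21 that was smaller than the spread between mice (two-sided exact permutation p 1.00). The differences within replicate numbers were −1.49 and 1.92. The group difference was 0.62 without Control replicate 1, 1.51 without Alb/TGF replicate 1, −0.19 without Control replicate 2 and −1.08 without Alb/TGF replicate 2. Under the stricter cell filter, which left 4 erythroblast-like cells in Control 1, it was −0.83, so its sign is not settled.

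Gene expression was compared within classes to ask which genes differ in erythroid cells of Alb/TGF mice, with the β-globin genes and Myc that the title names reported whatever their test. In erythroid-progenitor-like cells (4796213 to 16721512 UMIs per library) edgeR called 0 of 10251 genes, with 195 at an unadjusted p under 0.05. The 5 genes with the smallest p, none of which passed, were Prg2, Acot1, Vpreb1, Pax5 and Fn1. Prg2 (ENSMUSG00000027073), which encodes the eosinophil granule major basic protein, stood at 22.9 and 4.25 CPM in the Control libraries and 0.279 and 0.119 in the Alb/TGF libraries, a log2 fold change of −5.82 (SE 0.97). Acot1, an acyl-CoA thioesterase, was at 2.50 and 1.61 in Control and 6.28 and 11.7 in Alb/TGF (log2 fold change 2.29, SE 0.43). The pre-B-cell receptor gene Vpreb1 (−2.66, SE 0.55), the B-lineage factor Pax5 (−1.76, SE 0.48) and fibronectin, Fn1 (−1.15, SE 0.32), were lower in Alb/TGF of both numbers. With the replicate block 1 gene passed, Prg2. It was also a fixed marker of eosinophils and a top gene of the basophil- or mast-cell-like cluster. Whether its UMIs came from few cells was not tested. DESeq2 called 3 genes, Prg2 and the Y-linked Ddx3y and Eif2s3y, which only Alb/TGF 2 carried. The count was 19 without Control replicate 1, 41 without Alb/TGF replicate 1, 3 without Control replicate 2 (Prg2, Gatm and Apol11b) and 0 without Alb/TGF replicate 2. Genes of these short lists that no rule had set in advance were chosen after their values were seen.

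The adult globin genes did not pass in erythroid-progenitor-like cells, and their direction differed between replicate numbers. Hbb-bs (ENSMUSG00000052305, GRCm38 chromosome 7, 103826534 to 103828096, minus strand), an adult β-globin gene, was at 8816 CPM in Control 1, 16115 in Alb/TGF 1, 33652 in Control 2 and 15337 in Alb/TGF 2, a log2 fold change of −0.44 (SE 0.59) with 0.87 and −1.13 in the pairs. Without Control replicate 2 its fold change was 1.01, and the values of Hbb-bt, Hba-a1 and Hba-a2 also turned positive. Hbb-bt (ENSMUSG00000073940, chromosome 7, 103812524 to 103813996) was at −0.45 (SE 0.56), and the α-globin genes Hba-a1 (ENSMUSG00000069919, chromosome 11, 32283511 to 32284465) and Hba-a2 (ENSMUSG00000069917, chromosome 11, 32296489 to 32297298) at −0.58 (SE 0.58) and −0.45 (SE 0.59). The members of each pair are nearly identical, so the assignment of reads between Hbb-bs and Hbb-bt, and between Hba-a1 and Hba-a2, is uncertain, and sums are used below. In erythroblast-like cells β-globin made up 39.2% ± 5.49 of UMIs in Control and 39.4% ± 0.0298 in Alb/TGF, and α-globin 24.3% ± 3.63 and 22.2% ± 0.304 (SD, n = 2 each). As background, the β-globin share of T-cell-like cells was between 0.00569% and 0.268% and that of neutrophil-like cells between 0.0129% and 0.0728%. The ratio of β- to α-globin UMIs in erythroblast-like cells was 1.62 and 1.60 in Control and 1.75 and 1.79 in Alb/TGF, or 1.61 ± 0.02 against 1.77 ± 0.02 (SD, n = 2 each, two-sided exact permutation p 0.333). The 2 groups did not overlap for this ratio in erythroid-progenitor-like cells either (1.86 ± 0.06 against 1.96 ± 0.08, exact permutation p 0.333), nor in neutrophil-like cells (1.57 and 1.67), where the globin RNA is background. In progenitor-like cells the gap was between 1.895 and 1.904, and it closed under the stricter filter, with 1.96 in Control 1 above 1.94 in Alb/TGF 1. Within the early cluster the groups overlapped, at 1.52 and 1.78 in Control and 1.61 and 1.67 in Alb/TGF, and within the later cluster they did not (1.91 and 1.82 against 1.92 and 2.02, exact permutation p 0.333).

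Myc (ENSMUSG00000022346, GRCm38 chromosome 15, 61985391 to 61990374, plus strand), which encodes a growth-promoting transcription factor, was at 71.0 ± 21.7 CPM in Control and 79.4 ± 9.46 in Alb/TGF erythroid-progenitor-like cells (SD, n = 2 each, two-sided exact permutation p 1.00). Its edgeR log2 fold change was 0.26 (SE 0.23), with −0.25 and 0.63 in the pairs. Within the early progenitor cluster Myc stood at 130 ± 23.6 and 128 ± 3.13, and within the later one at 28.8 ± 16.9 and 22.4 ± 8.50. In HSPC-like cells it was 198 ± 20.5 in Control and 160 ± 8.25 in Alb/TGF, lower in both numbers (exact permutation p 0.333). Neutrophil-like cells, as background, held 1.15 and 1.09 CPM. In erythroblast-like cells Myc had 0 UMIs in every library, which allows up to 23.3, 3.80, 2.81 and 18.7 CPM in Control 1, Alb/TGF 1, Control 2 and Alb/TGF 2. The other erythroid genes named in advance also did not pass in progenitor-like cells, with log2 fold changes of −0.45 for Slc4a1, −0.36 for the heme synthesis enzyme gene Alas2, −0.29 for the transferrin receptor gene Tfrc and −0.20 for the erythroid factor gene Gata1. Values were 0.24 for the TGF-β feedback inhibitor gene Smad7, 0.17 for Tgfb1, −0.09 for the fetal globin repressor gene Bcl11a, −0.05 for Klf1 and 0.00 for the erythropoietin receptor gene Epor. Their SEs ran from 0.19 to 0.36. Signs turned without Control replicate 2 for Slc4a1, Alas2, Smad7, Tgfb1 and Epor, without Alb/TGF replicate 1 for Tgfb1 and Epor, and without Alb/TGF replicate 2 for Klf1.

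**Figure D3:**
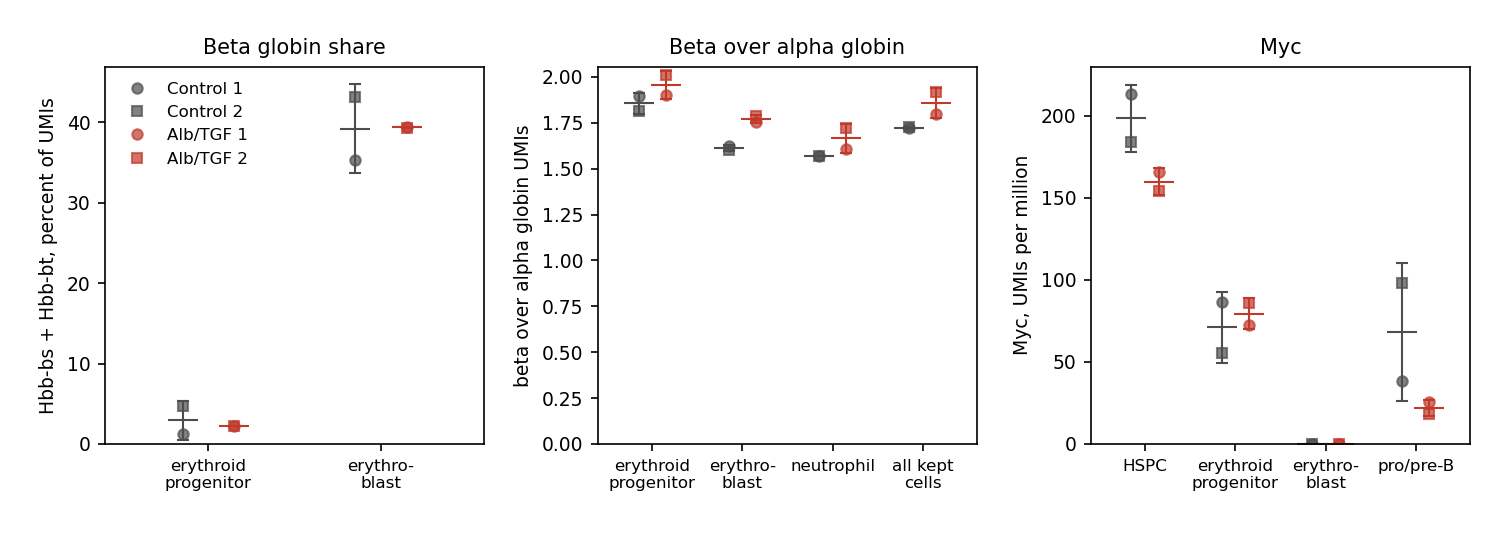
β-globin share of UMIs, the ratio of β- to α-globin UMIs, and Myc in CPM by class, with 1 point per library, and group means with bars of 1 SD (n = 2). The ratio in erythroblast-like cells was 1.62 and 1.60 in Control and 1.75 and 1.79 in Alb/TGF.

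In erythroblast-like cells (128671 to 1066703 UMIs per library) edgeR called 0 of 1796 genes, with 14 at an unadjusted p under 0.05, and DESeq2 called 0. The smallest p belonged to Tmsb10, Hmox1, Apol11b, Apoe and Usp18, none of which passed. Tmsb10, an actin-binding thymosin gene, was at 15.5 and 10.3 CPM in Control and 50.6 and 143 in Alb/TGF (log2 fold change 2.64, SE 0.69). Hmox1, the heme-degrading oxygenase gene, was at 171 and 91.9 in Control and 30.4 and 0 in Alb/TGF (−2.74, SE 0.74), and Apol11b, an apolipoprotein L family gene, at 15.5 and 54.4 in Control and 137 and 417 in Alb/TGF (2.34, SE 0.63). Apoe and the interferon-induced Usp18 were lower, by −2.52 (SE 0.87) and −2.80 (SE 1.01). Hmox1 was also a fixed marker of macrophages, and Apoe a top gene of a macrophage-like cluster at the finer clustering. All 7 macrophage markers tested here were lower in both numbers, and without Hmox1 they summed to 521 and 166 CPM in Control 1 and 2 and 167 and 18.7 in Alb/TGF 1 and 2, a sum taken after the data were seen. With the replicate block 2 genes passed, Hmox1 and Apol11b, both among those the rule named. In this class deviations correlated by −0.173 between libraries of equal number, which gives no support for pairing by number. Both genes also passed with the replicate numbers of the Alb/TGF libraries swapped (−2.74 and 2.06), a fit added after the data were seen. Leaving out a library gave 1 gene without Control replicate 1 (Gm5483), 3 without Alb/TGF replicate 1 (Apol11b, Hmox1 and Xist), 1 without Control replicate 2 (Chil3) and 1 without Alb/TGF replicate 2 (Vpreb3), the ones outside the rule chosen after their values were seen. Of the erythroid genes named in advance, Alas2 was at −0.43 (SE 0.37), Slc4a1 at −0.28, Tfrc at 0.19, Epor at 0.39, Klf1 at 0.22, Hbb-bs at −0.26, Hbb-bt at −0.13, Hba-a1 at −0.36 and Hba-a2 at −0.37, and none passed. The sign of Slc4a1 turned without Alb/TGF replicate 2 and that of Hbb-bt without Control replicate 2. Gata1, Tgfb1, Bcl11a, Smad7 and Myc had too few UMIs to be tested. In data simulated with the dispersion trend of these libraries, changed genes were drawn from those with a log2 mean CPM of at least 5. The same test recovered 8.96% of 2-fold, 41.8% of 4-fold and 84.8% of 8-fold changes in erythroblast-like cells. In progenitor-like cells it recovered 68.7%, 100% and 100%. These rates do not cover rarer genes or genes that vary more than the trend.

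Fixed gene lists were then compared to ask which programs moved as groups in erythroid cells. By camera with its preset correlation, 13 of 28 lists passed in erythroid-progenitor-like cells, 7 higher and 6 lower in Alb/TGF, and no list in any class passed after adjustment with the estimated correlation or with fry. Genes of class I antigen presentation were higher, with all 12 measured members positive, a median log2 fold change of 0.81 and 7 members passing when adjusted over the list alone (adjusted p 2.75e-12, estimated-correlation p 0.126). Examples were the class I gene H2-K1 (1.18) and the immunoproteasome genes Psmb9 (1.42) and Psmb8 (1.22), larger in replicate number 2 (1.64, 1.98 and 1.96) than in number 1 (0.34, 0.17 and −0.01). Genes of the unfolded protein and integrated stress response were higher in 20 of 22 members, median 0.45, such as the serine synthesis genes Phgdh (0.92) and Psat1 (0.97), which stood at 0.05 and −0.19 in replicate number 1, with 0 adjusted over the list alone (adjusted p 7.05e-09, estimated-correlation p 0.2004). Myc target genes were higher in 48 of 57, median 0.24, such as the spermidine synthase gene Srm (0.42) and Mrto4 (0.42), again with 0 adjusted over the list alone (adjusted p 2.38e-07, estimated-correlation p 0.237). Ribosomal protein genes were positive in 77 of 78 (median 0.21), glycolysis and hypoxia genes in 18 of 23 (median 0.26, with Vegfa at 0.90), class II genes in 6 of 8 (median 0.30) and NF-kB and inflammatory genes in 9 of 13 (median 0.25, with Il1b at 1.53). Their adjusted p values were 6.97e-04, 0.00384, 0.00618 and 0.0180, with estimated-correlation p of 0.604, 0.222, 0.185 and 0.117 and 0 members adjusted over the list alone.

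The lists that were lower in erythroid-progenitor-like cells held genes of the red-cell program, of the cell cycle and of other lineages. Red-cell membrane genes were negative in 20 of 23 members, median −0.26, including Add2 (−0.41), Epb42 (−0.43) and Gypc (−0.32), the last 2 slightly positive in replicate number 1 (0.27 and 0.03), with 0 passing when adjusted over the list alone (adjusted p 1.97e-04, estimated-correlation p 0.288). Erythroid transcription factor genes were negative in 18 of 22, median −0.16, among them Sox6 (−0.51), E2f2 (−0.52), Nfe2 (−0.31) and Tal1 (−0.31), with 0 adjusted over the list alone (adjusted p 0.0145, estimated-correlation p 0.389). The fold changes of E2f2 were −0.05 and −1.20 in replicate numbers 1 and 2, and those of Sox6 −0.12 and −0.94. S phase genes were negative in 32 of 42 (median −0.14, adjusted p 0.00618, estimated-correlation p 0.468) and G2 and M phase genes in 44 of 52 (median −0.14, adjusted p 0.00363, estimated-correlation p 0.484), with 0 members adjusted over the list alone in both. B lymphopoiesis genes were negative in 12 of 14, median −0.58, with 3 adjusted over the list alone, including Vpreb1 and Il7r (−1.67; adjusted p 2.14e-06, estimated-correlation p 0.0629). Neutrophil granule genes were negative in 19 of 20, median −0.46, such as Mpo (−0.94; adjusted p 6.04e-05, estimated-correlation p 0.368, 0 adjusted over the list alone). The list of TGF-β response genes did not pass, with 14 of 23 positive, a median of 0.02 and an adjusted p of 0.922, while single members lay at −1.15 (Fn1), 1.19 (the cell-cycle inhibitor gene Cdkn1a) and 0.65 (Tgfbr2). Heme synthesis (adjusted p 0.0529), oxidative phosphorylation (0.0698) and interferon response genes (0.101) did not pass, but did with the replicate block, at 0.0250, 0.00280 and 0.0328 (blocked estimated-correlation p 0.512, 0.422 and 0.267, 0 members adjusted over the list alone). None of these 3 passed after adjustment with the estimated correlation. The remaining lists did not pass either, namely histones (adjusted p 0.141), terminal erythroid clearance (0.159), iron handling (0.289), the Myc network (0.387), immediate early genes (0.425), antioxidant and Nrf2 genes (0.523), p53 and apoptosis (0.623), erythropoietin signalling (0.794), adult globins (0.861), chemokine and marrow retention genes (0.920) and mitochondrially encoded genes (1.00). The chemokine list had a negative median and a positive mean and test, and the mitochondrially encoded list a positive median and mean and a negative test. Embryonic globins and sex-linked genes had fewer than 3 members measured in every class and were not tested as sets.

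The class joins 2 clusters whose mix differed between libraries, with 141 early and 98 later cells in Control 1, 192 and 187 in Alb/TGF 1, 328 and 428 in Control 2 and 235 and 115 in Alb/TGF 2. Camera was therefore run within each cluster alone, a test added after the data were seen, and passed 6 of 28 lists in the early and 7 of 28 in the later cluster. Class I antigen presentation was higher in both (adjusted p 6.92e-10 and 8.58e-12, estimated-correlation p 0.142 and 0.0900, 0 and 1 members adjusted over the list alone). So were the unfolded protein and integrated stress genes (adjusted p 7.67e-06 and 5.74e-12, estimated-correlation p 0.198 and 0.174) and ribosomal protein genes (adjusted p 9.05e-06 and 0.00225, estimated-correlation p 0.530 and 0.641), with 0 adjusted over the list alone. Myc targets passed only in the later cluster (adjusted p 6.52e-07 against 0.0873, estimated-correlation p 0.147 there, 0 adjusted over the list alone). Histone genes were higher in both (adjusted p 4.26e-06 and 0.00176, estimated-correlation p 0.0317 and 0.376), oxidative phosphorylation genes passed, higher, in the early cluster (adjusted p 0.00146, estimated-correlation p 0.534) and NF-kB and inflammatory genes in the later one (adjusted p 0.00640, estimated-correlation p 0.0814), with 0 adjusted over the list alone. Neutrophil granule and B lymphopoiesis genes had negative medians in both clusters. The granule list passed in the early one (median −0.93 against −0.15, adjusted p 1.01e-15, estimated-correlation p 0.159, 6 adjusted over the list alone). The B lymphopoiesis list passed in the later one (−0.35 against −0.27, adjusted p 0.00207, estimated-correlation p 0.151, 1 adjusted over the list alone). Differences between the clusters were not tested. No list passed in either cluster after adjustment with the estimated correlation. The other 6 lists called in the summed class passed in neither. Early and later medians were −0.03 and −0.09 for red-cell membrane genes (−0.26 in the class), −0.09 and −0.10 for erythroid transcription factors (−0.16), 0.06 and −0.03 for S phase genes (−0.14), and 0.03 and −0.03 for G2 and M phase genes (−0.14). They were 0.22 and 0.16 for glycolysis and hypoxia genes (0.26 in the class) and −0.03 and 0.56 for class II genes (0.30).

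In erythroblast-like cells 3 of 25 lists passed by camera. Ribosomal protein genes were higher in 72 of 78 members, median 0.36, such as Rpl4 (1.06) and Rps19 (0.77), with 0 adjusted over the list alone (adjusted p 1.12e-09, estimated-correlation p 0.103). Interferon response genes were lower in all 14 measured, median −0.74, including Usp18, Cmpk2 (−1.62) and Isg15 (−1.07), a ubiquitin-like antiviral protein gene (adjusted p 7.72e-04, estimated-correlation p 0.190, 0 adjusted over the list alone). Neutrophil granule genes were lower in 15 of 19, median −0.49 (adjusted p 2.28e-04, estimated-correlation p 0.219, 0 adjusted over the list alone). The antioxidant and Nrf2 list passed only with the replicate block, at 0.0173 (blocked estimated-correlation p 0.203, not passing after adjustment), and held 1 gene lower when adjusted over the list alone, Hmox1, beside Prdx1 (−1.36). Hmox1 moved with the other macrophage markers, as above.

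Stem and progenitor cells were compared to ask whether changes reach earlier cells, and edgeR without the replicate block called genes there. In HSPC-like cells (65 to 118 per library) edgeR called 4 of 9388 genes, all adult globins and all lower in Alb/TGF, with 229 at an unadjusted p under 0.05. Hba-a2 fell from 276 and 227 CPM in Control to 14.6 and 5.64 in Alb/TGF (log2 fold change −4.69, SE 0.33, adjusted p 5.35e-05), Hbb-bs from 740 and 555 to 43.8 and 19.0 (−4.40, SE 0.33, adjusted p 8.60e-05), Hba-a1 by −4.63 (SE 0.44, adjusted p 6.75e-04) and Hbb-bt by −4.07 (SE 0.27, adjusted p 5.35e-05). The 2 cells with the most globin UMIs held 97.02% of the HSPC-like globin UMIs of Control 1 and 85.2% of those of Control 2, against 7.75% and 13.2% in Alb/TGF 1 and 2. Without those 2 cells per library 0 genes passed and the Hba-a2 fold change was −1.36. The globin UMIs left went in opposite directions, from 45.8 to 86.8 CPM in replicate number 1 and from 185 to 33.9 in number 2, and 0 genes passed under the stricter cell filter. A globin UMI was seen in 52.3%, 83.8%, 94.1% and 45.9% of HSPC-like cells in Control 1, Alb/TGF 1, Control 2 and Alb/TGF 2 at medians of 13178, 17889, 17311 and 14473 UMIs, and in 37.1%, 57.6%, 78.2% and 28.5% of mature-neutrophil-like cells, which should lack globin, at 2400.0, 2509, 2480.0 and 2787 UMIs. DESeq2 called 5 genes, the 4 globins and the platelet factor gene Pf4, higher in Alb/TGF (1.46), which was chosen after its value was seen. With the replicate block 14 genes passed, 12 lower and 2 higher (Pf4 and Serpine2), and the count was 9 without Control replicate 1, 39 without Alb/TGF replicate 1, 7 without Control replicate 2 and 10 without Alb/TGF replicate 2. Camera passed 9 lists, with G2 and M phase genes higher in 45 of 52 (median 0.17, adjusted p 2.41e-06, estimated-correlation p 0.374) and S phase genes in 32 of 42 (median 0.12, adjusted p 2.69e-04, estimated-correlation p 0.394) with 0 members adjusted over the list alone.

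The remaining 11 classes were compared gene by gene to ask whether the genotype acts outside the erythroid lineage. Together they gave 0 calls by edgeR, with between 90 (monocyte-like) and 249 (T-cell-like) genes per class at an unadjusted p under 0.05, and 29 calls by DESeq2, of which 13 were in T-cell-like cells. With the replicate block they gave 262 calls, 71 in plasmacytoid-dendritic-like, 69 in T-cell-like and 50 in B-cell-like cells. The count for the 11 classes was 532 without Control replicate 1, 834 without Alb/TGF replicate 1 (702 of them in T-cell-like cells), 82 without Control replicate 2 and 123 without Alb/TGF replicate 2. Smaller blocked counts were 18 each in basophil- or mast-cell-like and granulocyte-monocyte-progenitor-like cells, 14 in macrophage-like, 8 in monocyte-like and 0 in NK-cell-like cells. Immature-neutrophil-like cells had 5 (Mpo −0.69, Acot1 0.99, Immp1l 0.69, Igkc −0.78, Dnajc24 0.94), pro-B- or pre-B-like cells 5 (Ighg2b, Lgals3, Stfa1 and Pglyrp1 lower, Hba-a1 higher) and mature-neutrophil-like cells 4 (Igkc lower; Dusp1, Tsc22d3 and E230001N04Rik higher), the genes outside the rule chosen after their values were seen.

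In T-cell-like, B-cell-like and plasmacytoid-dendritic-like cells some of the 5 genes with the lowest p values were in the neutrophil granule list. These were Chil3, Camp and Ngp in the first class, Cd177 and Itgam in the second, and Mmp9 and Retnlg in the third. With the replicate block 14 of 69, 13 of 50 and 15 of 71 called genes were in that list. T-cell-like cells had less Chil3 (log2 fold change −4.93, SE 0.55), Camp (−5.18), Ngp (−5.34), Lgals3 (−3.10) and Inhba (−6.39), B-cell-like cells less Igsf6 (−3.32), Cd177 (−3.82), Itgam (−2.95) and Olfm4 (−3.46) and more Hba-a1 (0.92), and plasmacytoid-dendritic-like cells less Mmp9 (−1.88), Retnlg (−1.67), Asprv1 (−4.42), Crispld2 (−2.84) and Cd33 (−1.06), none of which edgeR called without the replicate block on all cells and all of which it called with it. DESeq2 called the 5 T-cell-like genes, Cd177 in B-cell-like cells, and Mmp9 and Retnlg in plasmacytoid-dendritic-like cells. Without the 2 B-cell-like cells per library with the most globin UMIs, globin RNA went from 503 to 875 CPM in replicate number 1. In number 2 it went from 649 to 118 CPM, so its direction there turned. The higher Hba-a1 of B-cell-like cells may thus rest on few cells, and Hba-a1 alone was not tested without them. Since 842 of the 890 T-cell-like cells of Alb/TGF 2 are in 1 cluster, that class was also fitted without it, which gave 13 genes, all lower and 9 of them granule genes, Chil3, Camp and Ngp included, and 102 with the block. As a list, neutrophil granule genes were lower by camera in T-cell-like (median −4.36, 14 of 17 lower adjusted over the list alone, estimated-correlation p 0.0605), B-cell-like (−2.88, 13 of 19, p 0.0587), NK-cell-like (−2.39, 15 of 18, p 0.170) and plasmacytoid-dendritic-like cells (−1.12, 7 of 20 lower and 1 higher, p 0.157). S100a8, a major neutrophil transcript, stood at 2639, 143, 16677 and 792 CPM in T-cell-like cells of Control 1, Alb/TGF 1, Control 2 and Alb/TGF 2, against 92295, 87759.9, 102563 and 103889 in mature-neutrophil-like cells. In NK-cell-like cells the smallest p belonged to Ccdc136 (−2.19), Ttn (−2.99), Dapl1 (1.97), Ifitm2 (−2.28) and the NK receptor gene Klra7 (−1.12). Pro-B- or pre-B-like cells had Serpinb6b (4.14), Fn1 (−2.87), Prg3 (1.84), Scd1 (−1.04) and Myc, which stood at 38.3 and 97.95 CPM in Control and 25.5 and 18.6 in Alb/TGF (−1.58, SE 0.42). In that class histone genes were higher in 18 of 19 (median 0.56, adjusted p 6.36e-11, estimated-correlation p 0.181) and Myc targets lower in 47 of 56 (median −0.21, adjusted p 3.82e-04, estimated-correlation p 0.458), with 0 members adjusted over the list alone.

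In the myeloid classes edgeR called no single gene without the replicate block. With the block it called H2-DMb1, H2-Ab1, Alas2 and Retnlg in macrophage-like cells, Stfa2l1 and Stfa1 in monocyte-like cells, and the 4 globin genes and Ear1 in basophil- or mast-cell-like cells. It also called Epx and Irf8 in granulocyte-monocyte-progenitor-like, Acot1 and Mpo in immature-neutrophil-like, and Tsc22d3 and Igkc in mature-neutrophil-like cells. DESeq2 called H2-Ab1 and Retnlg in macrophage-like, Stfa2l1 and Stfa1 in monocyte-like and Hbb-bs in basophil- or mast-cell-like cells. Macrophage-like cells had more of the class II genes H2-DMb1 (2.35, SE 0.52) and H2-Ab1 (2.25, SE 0.49) and of Alas2 (1.84), and less Retnlg (−2.00). The class II list was higher in all 7 members there (median 1.89, 6 adjusted over the list alone, adjusted p 2.15e-11, estimated-correlation p 0.0975), and by camera also in monocyte-like (0.57), immature-neutrophil-like (0.57), B-cell-like (0.38) and plasmacytoid-dendritic-like cells (0.28), with estimated-correlation p of 0.110, 0.0356, 0.269 and 0.0576 and 0 members adjusted over the list alone. Monocyte-like cells had less of the stefin A genes Stfa2l1 (−3.37, SE 0.32), Stfa1 (−4.18), Stfa2 (−4.43) and Stfa3 (−3.58), which were among the top genes of mature-neutrophil-like clusters and stood at 14.99 CPM or less in monocyte-like cells of every library, and more of the complement gene C1qc (1.78), whose sign turned at the finer clustering. Basophil- or mast-cell-like cells had less Hbb-bt (−2.76), Hbb-bs (−2.61), Hba-a1 (−2.21) and Hba-a2 (−2.60), and the eosinophil ribonuclease gene Ear1 was at 21.7 and 31.96 CPM in Control and 0 in both Alb/TGF libraries. Granulocyte-monocyte-progenitor-like cells had less of the eosinophil peroxidase gene Epx (−3.81), the lineage factor Irf8 (−1.56), Them7 (−2.73) and Ift122 (−1.64), and more Krtcap3 (1.09). In immature-neutrophil-like cells Acot1 (0.98, SE 0.18), Mylip (0.85) and Vill (0.45) were higher and Mpo (−0.68, SE 0.13) and Lgr4 (−0.93) lower. Mature-neutrophil-like cells had more of the glucocorticoid-induced Tsc22d3 (0.66) and Mbd4 (2.42), and less Igkc (−1.34), Lig1 (−1.93) and Mcm2 (−2.56). The TGF-β response list passed in this class alone, with 18 of 22 positive and a median of 0.10 (adjusted p 0.0493, estimated-correlation p 0.279, 0 adjusted over the list alone).

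Whole marrow sums, which also move with cell composition, were compared to ask what a bulk measurement would show. EdgeR called 0 of 14678 genes, with 208 at an unadjusted p under 0.05. The smallest p belonged to Adamts1 (log2 fold change 3.52), Slamf7 (0.96, SE 0.21), the plasma-cell chaperone gene Mzb1 (0.82, SE 0.18), Csn3 (4.59) and Dntt (0.91, SE 0.22), the terminal transferase gene of lymphoid precursors. DESeq2 called 4 genes, Ddx3y, Eif2s3y and the immunoglobulin genes Igkv4-50 and Igkv6-32, chosen after their values were seen, and edgeR called 16 without Alb/TGF replicate 1. B lymphopoiesis genes were higher in 20 of 22 members (median 0.62, adjusted p 6.35e-13, estimated-correlation p 0.167) and class II genes in all 11 (median 0.52, adjusted p 1.11e-08, estimated-correlation p 0.114), with 0 members adjusted over the list alone. Over all classes camera passed 108 of 417 tests, 61 higher and 47 lower, and with the replicate block 137, among them the same 108 in the same direction. With the estimated correlation, with fry and with the blocked estimated correlation 0 of the 417 passed.

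The last comparison asked whether the genotype effect in erythroblast-like cells differed from that in neutrophil-like cells, the most abundant other lineage. EdgeR called 0 of 9940 genes for the interaction, with 108 at an unadjusted p under 0.05. The smallest p belonged to Apoe (difference in log2 fold change −3.13, SE 0.89), Tle3, Hmox1 (−2.56, SE 0.78), Tmsb10 (2.51, SE 0.81) and the tetraspanin gene Cd9 (−3.00, SE 0.98), with Apoe and Hmox1 moving with macrophage markers, as above. Hbb-bs differed by 0.15 (SE 1.84). In data simulated with the dispersion trend of erythroblast-like cells in both classes, this test recovered 0% of 2-fold and 4-fold and 13.6% of 8-fold differences. The changed genes had a log2 mean CPM of at least 5 in erythroblast-like cells. The dispersion of neutrophil-like cells was not used, so the power of the test in these data is not known. Real differences may have gone undetected.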

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

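The 3 tests of the erythroid shares below were chosen only after the result was seen.

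Of all barcodes of Alb/TGF 1, 12.0% had under 200 genes and at least 50% globin UMIs and were left out by the filters. The share was at most 7.74% in a Control library (7.74% in Control 1, 6.18% in Control 2) and 1.11% in Alb/TGF 2. Barcodes above the mitochondrial limit made up 9.04% of Alb/TGF 1, against at most 7.72% in a Control library (7.72% in Control 1, 7.37% in Control 2) and 6.23% in Alb/TGF 2. Both lie outside the kept cells, and late erythroid cells with few other transcripts could be among the globin-rich barcodes. The erythroblast-like ratios of 6.28 and 0.135 in replicate numbers 1 and 2 thus describe kept cells only. In number 1 the globin-rich barcodes left out numbered 782 in Control and 908 in Alb/TGF, against 44 and 196 erythroblast-like cells kept. In number 2 they numbered 771 and 120, against 245 and 30. The size of the ratio in number 1 therefore depends on the gene minimum, and a ratio with these barcodes counted was not tested.

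Erythroid cells were more frequent in Alb/TGF than in Control in replicate number 1 and less frequent in number 2, and the difference grew from the early progenitor cluster to erythroblast-like cells. The erythroblast-like ratios of 6.28 and 0.135 leave a change shared by both Alb/TGF animals open in either direction, with a mean log2 ratio of −0.12 and a 95% t interval from −35.3 to 35.1. Sex is argued against for number 1, where both libraries had Xist at 867 CPM or more, and the Controls, both with the female pattern, held 0.535% and 2.29%. Unequal loss of hemoglobin-rich cells in red-cell lysis stays open: the absolute log2 ratio was larger in erythroblast-like cells than in the earliest cluster by 1.71 and 2.55, but this grading is what raised the explanation, and no marrow without lysis was measured. Mouse and handling also stay open, and in number 2 sex, as Alb/TGF 2 alone had the male pattern, so these shares give no evidence for or against defective erythropoiesis in this line.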

How the results depend on the processing

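Of 155 values of the comparisons under other settings, 103 kept their call or moved by less than 1 SD between mice, 7 were weaker, 34 stronger, 11 moved and 0 called values reversed. Uncalled signs did turn: the log2 stage ratio difference, 0.21, was −0.83 with the stricter filter and −1.08 to 1.51 when leaving out a library. The replicate block gave 1 gene in erythroid-progenitor-like, 2 in erythroblast-like, 14 in HSPC-like cells and 262 in the other classes together, put the erythroblast-like share at −0.11 and the lists called at 137, and changed no other call. DESeq2 gave 3 genes in erythroid-progenitor-like cells, 29 in the other classes and 4 in whole marrow. Without the low-count filter the counts were 34 in erythroid-progenitor-like cells, 28 in HSPC-like cells, 633 in the other classes and 44 in whole marrow. Leaving out a library, where the lone sample of a group is assumed to vary like the others, gave 0 to 41 genes in erythroid-progenitor-like, 1 to 3 in erythroblast-like, 7 to 39 in HSPC-like cells, 82 to 834 in the other classes and 0 to 16 in whole marrow. It gave 0 to 1 called class shares, an erythroblast-like share of −2.19 to 1.77, an erythroid-progenitor-like share of −0.48 to 0.80 and Hbb-bs in erythroid-progenitor-like cells of −1.16 to 1.01. As a share of non-neutrophil cells the erythroblast-like value was −0.11 and the progenitor-like value −0.35, and with TMM −0.033 and −0.22. HSPC-like cells gave 0 genes with globin genes left out, 0 with the stricter filter, and 0 without the 2 globin-highest cells (8 with the block). With doublets kept, the other classes gave 3 genes. The stricter filter moved the β- to α-globin difference in erythroblast-like cells from 0.156 to 0.181 and left too few erythroblast-like cells (4 in Control 1) for a gene fit. Crossed pairing gave 12, 2, 7 and 55 genes in erythroid-progenitor-like, erythroblast-like, HSPC-like and the other classes. Erythroid-progenitor-like lists called fell from 13 to 6 and 7 within its 2 clusters. Lists called fell from 108 to 0 with the estimated correlation and to 0 with fry. Added after the data were seen were crossed pairing, the fits without the T-cell cluster, with cells left out, the lists within clusters, and all whole-marrow alternatives except the block and leaving out a library.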

Other observations

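The test of T-cell receptor use and the comparison across animals were chosen only after the result was seen, while the doublet test and both tests of granule RNA were set beforehand, except for the look at single classes.

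A T-cell-like cluster made up 8.69% of Alb/TGF 2 and 0.0243%, 0.0515% and 0.0842% of Control 1, Alb/TGF 1 and Control 2. Its 842 cells in Alb/TGF 2 carried Cd8a in 83.0% of cells, Ccl5 in 99.2% and the developmental factor gene Sox4 in 84.2% (39.5%, 11.9% and 2.21% of other T-cell-like cells), at medians of 4016.5 and 3920.0 UMIs, and mature-neutrophil-like cells had Cd8a in 0.0469%. Of the Trbv UMIs 81.5% were Trbv2 (286 of 351, seen in 237 cells), against 19.7% for the most used gene of other T-cell-like cells. This may reflect expansion of 1 clone. The Trav UMIs were split between Trav7d-3 (58.0%) and Trav12-3 (34.2%), with 8 cells carrying both against 9.66 for independence. Separate clones with 1 of these genes each would give fewer cells with both, so the split does not speak against 1 clone. Doublets are argued against by a median Scrublet score at percentile 13.4 of the library's other cells (0.0174 against 0.0473, at medians of 4016.5 and 4683 UMIs), and a change shared by both Alb/TGF animals by the share of 0.0515% in Alb/TGF 1. It stays open whether there is 1 clone or more and whether this animal's genotype has any part in it.

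Neutrophil granule RNA was lower in B-, T-, NK- and plasmacytoid-dendritic-like cells of Alb/TGF, with a mean log2 fold change of −2.15 that leaned on Control 2 (−0.99 without it, −1.46 without Alb/TGF 1, −2.85 without Alb/TGF 2 and −3.32 without Control 1). Scrublet called 0.908% doublets in Control 2, at a score threshold of 0.393, and 2.36% to 3.66% in the other libraries, at 0.273 to 0.307. Whether doublets left in Control 2 add to its granule RNA was not tested. The 5% of cells with the most granule UMIs held 72.3% to 84.6% of them over the libraries, above the bound set against free RNA. That bound was set for the 4 classes pooled, and the share was 11.01% in NK-cell-like cells of Alb/TGF 2 and 14.3% in T-cell-like cells of Alb/TGF 1. Over the 4 classes 99.5%, 89.4%, 99.5% and 98.8% of cells had a granule UMI in Control 1, Alb/TGF 1, Control 2 and Alb/TGF 2. The medians were 6, 3, 7 and 5 UMIs per cell. Low counts were thus spread over most cells, so free RNA may be part of it, and its part in the fold change stays open. NK-cell-like cells did not follow the pattern in number 1, with 4407 CPM in Control 1 and 5530.4 in Alb/TGF 1. Cells joined to a neutrophil could carry it, but without the top 5% the fold change kept 77.6% of its size (−1.67, and −0.63 without Control 2), between the bounds set beforehand, so this test cannot tell. Without them the unblocked fits still called 0 genes, without Control replicate 2 (all cells) 0 granule genes were called in the 4 classes, and the blocked calls went from 69 to 0 in T-cell-like, 50 to 28 in B-cell-like, 71 to 51 in plasmacytoid-dendritic-like and 0 to 18 in NK-cell-like cells.

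Acot1 stood at 5.98, 6.80, 5.02 and 9.99 CPM in whole marrow in Control 1, Alb/TGF 1, Control 2 and Alb/TGF 2, and was higher in Alb/TGF of both numbers in erythroid-progenitor-like and immature-neutrophil-like cells. EdgeR called it in neither without the replicate block, and with the block in immature-neutrophil-like cells only (adjusted p 0.00836, and 0.798 in erythroid-progenitor-like cells). It was also called without Alb/TGF replicate 1 in both (2.72 in erythroid-progenitor-like and 1.14 in immature-neutrophil-like cells) and without Control replicate 1 in erythroid-progenitor-like cells (2.43). A result that did not pass is not shown to be unchanged, least of all with 2 mice per group.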
